A study of Mus musculus with 5 samples.

How the data were processed

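Total RNA of 5 samples was extracted with a column kit, fragmented, biotinylated and hybridised to whole-transcript mouse arrays, per the labels' protocols. The authors deposited 1 table of linear intensity values, with 28853 probe sets and 1 column per array. How these intensity values were background-corrected, summarised and normalized is not given in the sources used here. The sorted values of any pair of arrays agreed within 0.24 on the log2 scale, so the arrays had been brought to a similar distribution before they were deposited. The medians of the 5 columns were 192.0 (2i ESCs), 187.0 (S ESCs), 173.2 (2n 2i MEFs), 181.3 (4n 2i MEFs) and 170.2 (control MEFs) intensity units. Exact identity of many values between MEF arrays, and of none between ESC and MEF arrays, is described in the report. No detection calls were used, and arrays have no sequencing depth.

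Intensities were analysed as log2(value + 1). Of the probe sets, 21789 carried 1 gene symbol, 1621 several and 5443 none in the platform table. Symbols were updated through Entrez Gene numbers to the RefSeq gene table of assembly GRCm38.p6, which matched 21698 probe sets of 1 gene and was used for names and chromosome membership only. Probe sets of several genes named none, so some imprinted genes of the lists were not measured here. For the 999 genes with several probe sets, the one with the highest mean over the 5 arrays was used. No gene that is named had probe sets that disagreed in sign. A gene entered a comparison when its brighter array was at or above that array's floor, the median of the gene-named probe sets.

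Each pair of arrays was compared by log2 difference and a threshold of 2-fold, with no test, since each group had 1 array. The ESC arrays (2) were compared with the MEF arrays (3) with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), which left 3 residual degrees of freedom. In 5 simulated arrays with the spread of the data, this step recovered 68 of 100 genes changed by a log2 of 1.5 and 92 of 100 changed by 3, with 7 false calls among 11827 genes. The 30 gene lists, with 449 members of which 402 were measured, were fixed before the data were examined. For lists with at least 5 genes past the floor, the median was given with its percentile among 10000 random lists with the same number of genes from each of 20 brightness bins. These percentiles describe the arrays and are not tests, since genes are not replicates. In a check on 100 random lists of 15 genes per comparison, between 3 and 9 lay outside the central 95%, and at least 99 of 100 lists shifted by 0.5 lay above it. The overlap of differences that share the control array was compared with 100 simulations of unchanged arrays.

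The genes named were chosen by a rule set before the data were examined. For each pair of arrays it took the 12 highest and 12 lowest genes past the threshold and the floor, leaving out clone-named and predicted genes, receptor and immunoglobulin segments and small RNAs. For genes changed alike on both 2i MEF arrays it took 12 in each direction by the smaller difference, and for ESCs against MEFs 10 in each direction. Up to 4 members of each list per comparison, and any member of the imprinted, X inactivation and Y-linked lists, could also be named. Alternatives tried were no floor, a floor at the 75th percentile, quantile normalization, the mean of the probe sets of a gene, a pseudocount of 16, a threshold of 3-fold, leaving out each array, and an intensity trend with a robust prior. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.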

Results

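Expression in mouse embryonic stem cells (ESCs) and mouse embryonic fibroblasts (MEFs) was measured on 5 whole-transcript microarrays, 1 per group. The ESC groups were 2i ESCs and S ESCs. The MEF groups were control MEFs and the 2i MEFs named 2n and 4n. All cells came from F1 crosses of 129X1/SvJ and MSM/Ms mice. The name 2i usually stands for a medium with inhibitors of MEK and GSK3, kinases of the ERK and Wnt pathways. S, 2n and 4n are not spelled out in the labels and are used here as names only. The first number in the sample titles was 15 for both the 2i ESCs and the 2n 2i MEFs, 36 for the S ESCs, 2 for the 4n 2i MEFs and 4 for the control MEFs, so the pairs compared differed in more than their group name. The study's title concerns female ESCs and the retention of DNA methylation inherited from the gametes. The question behind the comparisons was taken to be how ESC culture, and passage of 2i ESCs into MEFs, went with expression of imprinted and other genes.

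Each array held 28853 probe sets, and 19938 genes were measured by a probe set of 1 gene. With 1 array per group there was no replicate, the number of arrays limits the precision, and no difference between a pair of arrays could be tested. Genes are therefore described as higher or lower on 1 array by at least 2-fold, among genes whose brighter array reached that array's floor, the median of its gene-named probe sets. The floors lay between 217.9 and 240.1 intensity units. Values below them contain an unknown part of background, so a fold against such a value depends on that background.

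The 2n 2i MEF and control MEF arrays were the most alike pair. Their log2 differences had an SD of 0.31 across 10131 genes, and 1.91% of these genes differed at least 2-fold. The 4n 2i MEF array stood farther away, with an SD of 0.54 from the 2n array (5.69% of genes at least 2-fold) and 0.65 from the control array (8.70%). The pair of ESC arrays differed with an SD of 0.51 (5.33%). Every pair of an ESC and a MEF array had an SD between 1.39 and 1.49. Identical deposited values stood in 45.4% of probe sets on the 2n and control MEF arrays, 37.4% on the 2n and 4n arrays and 37.9% on the 4n and control arrays. The share was 1.19% for the ESC arrays and 0 for any ESC array set against any MEF array. An exact difference of 0 between MEF arrays is thus a feature of the deposited values and is not read as measured equality.

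The largest contrast was between cell types. ESCs expressed the pluripotency network and MEFs the genes of connective tissue. Pou5f1 (Entrez Gene 18999), which encodes the transcription factor Oct4, was 122.5-fold higher in ESCs, at 13.06 ± 0.10 (log2, SD, n = 2) against 6.12 ± 0.06 (SD, n = 3) in MEFs, with an adjusted p of 6.32e-05 in limma. Postn (Entrez Gene 50706), encoding the matrix protein periostin, was 154.8-fold lower in ESCs, at 6.15 ± 0.64 (SD, n = 2) against 13.42 ± 0.15 (SD, n = 3), with an adjusted p of 0.000312 in limma. Of 11827 genes tested, 1970 were higher and 1925 lower in ESCs at an adjusted p under 0.05 and at least 2-fold.

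The other genes with the largest excess in ESCs were Dppa5a (log2 difference 7.88), an RNA-binding protein of early embryos, Nr0b1 (7.18), a nuclear receptor of the pluripotency network, Tdgf1 (7.18), a Nodal co-receptor, the homeobox factor Nanog (6.87), the zinc finger genes Zfp640 (6.65) and Zfp42 (6.33), Bex1 (6.50), the chromatin-associated Utf1 (6.49) and the F-box gene Fbxo15 (6.47). The largest deficits were in the small proteoglycans Aspn (-7.03) and Dcn (-5.79), the matrix-associated Ccdc80 (-6.23), the mesenchymal cadherin Cdh11 (-6.21), the aggrecan-cleaving protease Adamts5 (-6.09), the collagen Col12a1 (-5.82), the growth factors Tgfb3 (-5.69) and Ptn (-5.61), and Lox (-5.61), which crosslinks collagen and elastin. All had adjusted p values in limma between 5.63e-05 and 0.00931. Of these genes, Nr0b1, Tdgf1, Zfp640, Utf1, Fbxo15 and Lox had identical values on every MEF array (SD 0). Their limma p values, which include those at the ends of this range, thus hold no measured spread between MEF arrays.

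By list, 16 of 16 core pluripotency genes and 12 of 13 naive pluripotency genes were higher in ESCs and none lower. Of 12 genes of the DNA methylation machinery 10 were higher, among them Dnmt3l (log2 5.64), a cofactor of de novo methylation, and the demethylase Tet1 (3.71). Of 16 tested germline genes whose promoters are methylated in somatic cells, 15 were higher, among them the meiotic gene Hormad1 (4.64). Of the 28 measured, 14 reached the floor on each ESC array and 0 on any MEF array, so the floor favours this count. Of 17 cell cycle genes 13 were higher, among them the replication helicase subunit Mcm3 (2.23), and 6 of 13 genes of glycolysis and hypoxia were higher. Among epithelial markers 5 of 9 were higher, led by the adhesion molecule Cdh1 (6.05), and 1 was lower. In the opposite direction, 20 of 22 fibroblast markers, 10 of 11 contractile and TGF-beta response genes and 20 of 25 Hox genes were lower in ESCs, while 2 Hox genes were higher. Of 37 measured Hox genes, 3 and 4 reached the floor on the ESC arrays and 18 to 23 on the MEF arrays, so the floor favours lower calls there. With p adjusted over the list alone, the counts of higher and lower genes in these lists were the same except for 21 fibroblast markers. Imprinted genes were less uniform. Of 13 paternally expressed genes with maternal germline methylation 3 were lower and none higher, among them Airn (-3.91), the antisense transcript that overlaps Igf2r, and Ndn (-2.57). Of 11 maternally expressed ones 2 were higher, among them Ascl2 (1.69), and 2 lower, among them H13 (-2.53). Adjusted over each list alone these counts were the same. Xist, the RNA that coats the inactive X chromosome, was lower in ESCs (log2 difference -4.71, adjusted p = 0.00534 in limma).

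These calls were made with limma over 2 and 3 arrays whose spread is that between conditions, not between replicates of a condition. The labels do not say that the samples came from separate cultures or embryos. Any part of a difference that came from computing the values of each cell type apart was not measured. Of the genes tested, 33.2% had identical values on at least 2 MEF arrays and so no measured spread between those arrays. Without them 1031 genes were higher and 1590 lower in ESCs.

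The 2i ESCs and S ESCs shared their core pluripotency genes and differed in ERK pathway genes, de novo methyltransferases, connective tissue genes and X-linked genes. On the 2i array 292 of 10493 genes were at least 2-fold higher and 267 lower than on the S array. The germ cell RNA-binding protein gene Dazl (Entrez Gene 13164) was 13.3-fold higher on the 2i array (5692 against 427 intensity units). The ERK phosphatase gene Dusp6 (Entrez Gene 67603) was 8.23-fold lower (156.7 against 1297), and Dnmt3b, a de novo DNA methyltransferase, had a log2 difference of -2.16 (373 against 1667).

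After Dazl, the genes with the largest excess on the 2i array were Iqca (12.3-fold), the lens crystallin gene Crygd (11.0), Pglyrp1 (9.55), which binds bacterial peptidoglycan, Gpr143 (9.53), a pigment cell receptor, the calcium-binding S100a1 (7.88), the imprinted zinc finger gene Plagl1 (7.86), Xlr (7.83), the RNA export gene Nxf3 (7.61), Pramel7 (7.04), a gene of the early embryo, the aspartate metabolism gene Aspa (6.96) and the alcohol dehydrogenase Adh1 (6.69). The probe sets of Iqca disagreed in size, and their mean gave a log2 difference of 1.04. The genes with the largest deficit were Thbs1 (14.7-fold), encoding the matrix protein thrombospondin 1, the proteoglycan Bgn (14.1), the matrix glycoprotein Tnc (13.8), the imprinted growth regulator Phlda2 (13.1), the neuronal Crmp1 (11.7), the epithelial splicing regulator Esrp1 (10.3), Fndc3c1 (10.1), Lox (9.31), the neurofilament gene Ina (8.53), Dusp6, smooth muscle actin Acta2 (6.45) and Calml4 (6.37).

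Of 17 ERK pathway response genes, 5 were at least 2-fold lower on the 2i array, 12 lay within 2-fold and none was higher. The 5 were Dusp6, the transcription factor genes Egr1 (log2 -2.34), Etv4 (-1.82) and Myc (-1.54), and the pathway inhibitor Spry4 (-2.23). The list's median was -0.63, below all 10000 random lists of matched brightness. Immediate early and heat shock genes had a median of -0.69 (percentile 0.02), with Jun at -1.42. Of 8 Wnt pathway targets, 1 was at least 2-fold higher, Tnfrsf19 (1.07), and the median was at percentile 52.6.

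All 16 core pluripotency genes passed the floor, and 15 of them lay within 2-fold. The exception was the RNA-binding protein gene Lin28a (-1.56). The list's median was -0.23 (percentile 0.32). All 13 naive pluripotency genes lay within 2-fold, 11 of them higher on the 2i array, with a median of 0.33 (percentile 99.97) and the largest difference in Prdm14 (0.75). Of 15 primed and early lineage genes 3 were at least 2-fold lower, Dnmt3b, the keratin gene Krt8 (-1.31) and the methyltransferase gene Dnmt3a (-1.09), and the median was -0.40 (percentile 0.06). In the DNA methylation machinery list the same methyltransferases were the 2 of 12 genes beyond 2-fold. Germline genes with methylated promoters went both ways. Of 16, 3 were at least 2-fold higher, Dazl (3.73) and the tubulin genes Tuba3b (2.36) and Tuba3a (1.98), and 3 lower, the piRNA pathway gene Mael (-2.41), the synaptonemal complex gene Sycp3 (-2.35) and D1Pas1 (-1.29). None of 4 genes of the 2-cell stage reached the floor.

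Several lists of other lineages were lower on the 2i array. The median was -0.91 for contractile and TGF-beta response genes (4 of 11 at least 2-fold lower, below all random lists), -0.90 for epithelial genes (3 of 7, among them Epcam at -1.57), -0.63 for neural and glial genes (1 of 6, percentile 0.02) and -0.47 for fibroblast markers (4 of 13, percentile 0.06, among them Dcn at -1.91). Lists with fewer than 5 genes past the floor had no median and went both ways. By any amount, all 4 endothelial genes, all 3 cartilage and bone genes and 3 of 4 Hox genes were higher on the 2i array, and all 3 skeletal muscle genes lower. Beyond 2-fold these were only Matn1 (1.48), Hoxc12 (1.31) and Des (-1.42). Beside these, 113 of 127 genes that were bright on the control MEF array and under the floor on the 2i ESC array were higher on the S than on the 2i ESC array. That choice of genes favours the S array. With the reverse choice, genes under the floor on the S array, 59 of 88 were still higher on the S array and 29 on the 2i array. In the first set the excess on the S array had a median of 1.65% of the control MEF intensity, and 14 fibroblast and contractile markers among them ranged from 0.457% (Postn) to 16.4% (Thbs1). Of 13 genes of glycolysis and hypoxia, 1 was at least 2-fold higher on the 2i array, the stress-response gene Ndrg1 (1.15), and 12 lay within 2-fold. By any amount 10 were higher and 3 lower, with a median of 0.20 (percentile 99.7). Medians of the cell cycle, p53, cholesterol synthesis and housekeeping lists lay within the central 95% of random lists.

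Of the imprinted genes on the ESC arrays, Plagl1 (2.97) was at least 2-fold higher on the 2i array and Nnat (-1.78), a small membrane protein gene of neural tissue, lower. The other 9 paternally expressed genes with maternal germline methylation past the floor lay within 2-fold. Among 10 maternally expressed genes with maternal germline methylation, Phlda2 (-3.71), the transporter gene Slc22a18 (-1.52) and the growth factor receptor adaptor gene Grb10 (-1.47) were lower and none was higher, with a median of -0.27 (percentile 3.27). Of genes with paternal germline methylation, the noncoding RNA gene Meg3 was higher (1.30), the growth factor gene Igf2 lower (-1.88), and Dlk1 lay within 2-fold (0.11). Igf2 lay under the floor on the 2i array, at 184.4 against 682.6 intensity units on the S array.

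X-linked genes were shifted as a group. Of 367 X-linked genes, 43 were at least 2-fold higher on the 2i ESC array and 7 lower, and 270 were higher by any amount. Their median was 0.29, above all 10000 random lists, while the medians of 19 autosomes ran from -0.08 to 0.02. Xist lay below the floor on both ESC arrays. Of 7 Y-linked genes only Sry, at 251.2 intensity units on the 2i ESC array, reached a floor on an ESC array, and none did on a MEF array.

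**Figure D1:**
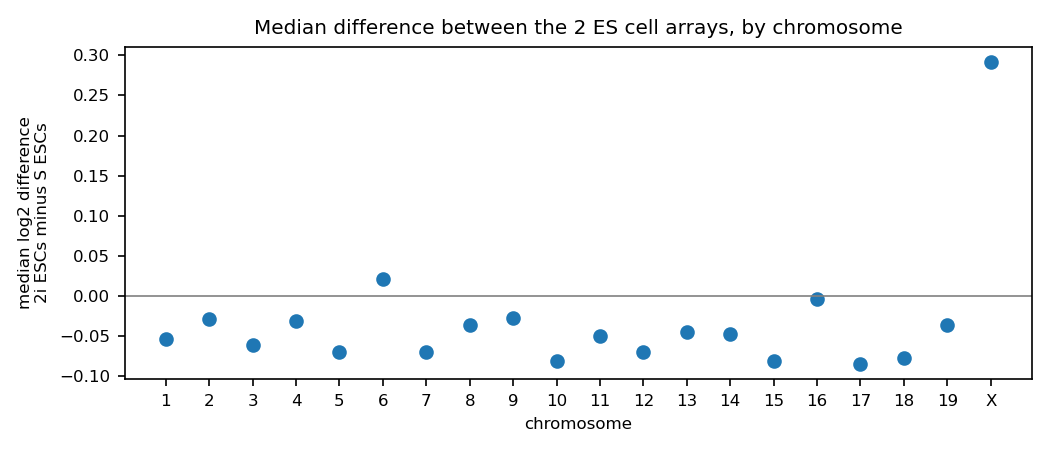
Median log2 difference between the 2i ESC and S ESC arrays over the genes past the floor on each chromosome, 1 point per chromosome. The X chromosome lies at 0.29 and the 19 autosomes between -0.08 and 0.02.

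The 2n 2i MEFs resembled control MEFs except in a limited set of genes, a small part of them imprinted. On the 2n array 150 of 10131 genes were at least 2-fold higher and 44 lower than on the control array. Mest (Entrez Gene 17294), a paternally expressed imprinted gene, was 5.05-fold higher (2978 against 588.8 intensity units). Igf2r (Entrez Gene 16004), the maternally expressed receptor that clears the growth factor Igf2, was 2.91-fold lower (1048 against 3048), and Grb10 2.59-fold lower (2326 against 6018).

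Every one of 13 paternally expressed genes with maternal germline methylation past the floor was higher on the 2n array, 3 of them at least 2-fold. These were Mest (log2 2.34), Plagl1 (1.33) and the retrotransposon-derived Peg10 (1.16). The list's median of 0.33 lay above all random lists. Of 8 maternally expressed genes with maternal germline methylation, 7 were lower, 2 of them at least 2-fold (Igf2r at -1.54 and Grb10 at -1.37), and Trappc9 was identical. This median was -0.21 (percentile 0.12). Among genes with paternal germline methylation Meg3 was lower (-1.04), and Igf2 (-0.27) and Dlk1 (0.00) lay within 2-fold.

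**Figure D2:**
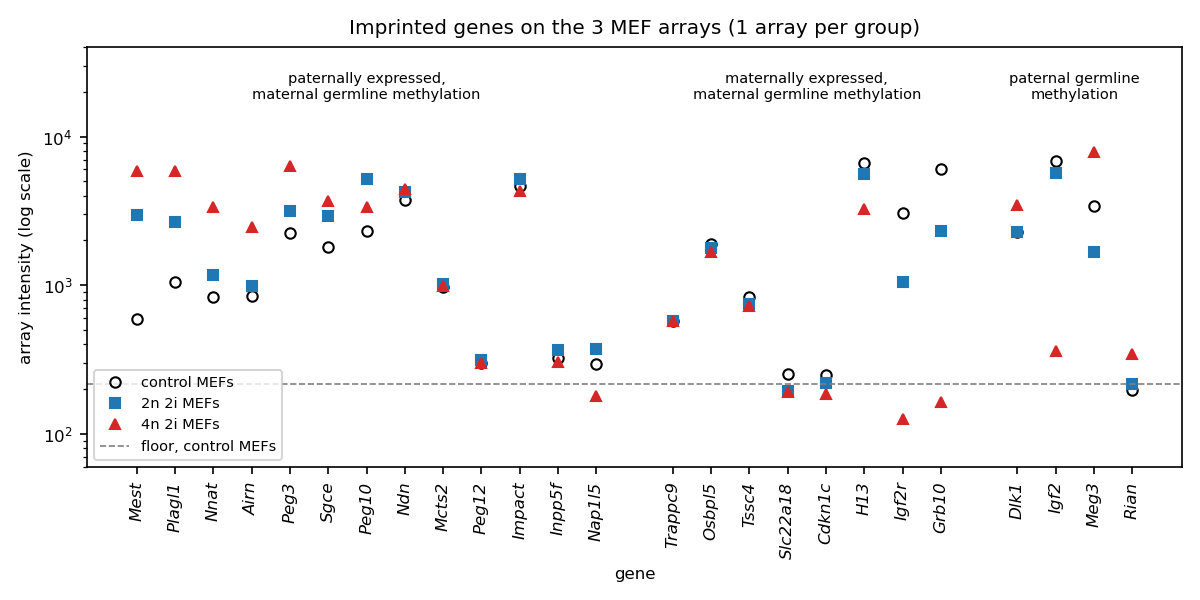
Array intensity, on a log axis, of each imprinted gene that passed the floor in the comparison of 4n 2i and control MEFs, with 1 symbol per MEF array and the control array's floor as a dashed line. Mest, Plagl1, Igf2r and Grb10 lie on the 2n array between their control and 4n values, while Meg3 lies below the control on the 2n array and above it on the 4n array.

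The other genes with the largest excess on the 2n array were the interleukin 1 receptor antagonist Il1rn (12.8-fold), the muscle intermediate filament gene Des (7.59), the mesothelial and urothelial Upk3b (7.43), the morphogens Bmp4 (7.37) and Bmp5, Lrrn4 (6.43), the carbonyl reductase Cbr2 (6.38), the granzyme Gzmd (6.30), the endothelial sialomucin Emcn (6.06), the transcription factor gene Sim2 (5.95), the retrotransposon-derived Rtl3 (5.79) and Smoc1 (5.35). The largest deficits were in the prolactin family gene Prl3a1 (6.62-fold), S100a7a (5.31), the receptor gene Gpr149 (3.66), the peptide hormone gene Cck (3.54), Cyp4a12b (3.50), Adam33 (3.37), the ATP-hydrolysing Entpd1 (3.34), the citrate transporter Slc13a5 (3.26), Igf2r, Lce1h (2.79), the integrin Itga4 (2.71) and Grb10.

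Several lists shifted with at most 1 gene beyond 2-fold in either direction. All 17 cell cycle genes were higher on the 2n array, none by 2-fold, with a median of 0.43 above all random lists and the kinesin gene Kif11 at 0.57. Of 8 genes of the DNA methylation machinery 7 were higher, with a median of 0.40 above all random lists. Fibroblast markers had a median of 0.13 (above all random lists), with the protease gene Fap at 1.60. Neural and glial genes had a median of 0.45 (percentile 99.97), with Nes at 1.70. All 7 interferon response genes were lower (median -0.38, percentile 0.01), with Ifit1 at -1.11. ERK pathway response genes had a median of -0.18, below all random lists, with 1 of 19 at least 2-fold lower, the phosphatase gene Dusp4 (-1.17). Glycolysis and hypoxia genes had a median of 0.13 (percentile 99.5), with the mitophagy gene Bnip3 at 1.54, and immediate early and heat shock genes 0.12 (percentile 97.6). The median was -0.16 for naive pluripotency genes (percentile 1.74), with Klf4 at -0.90, and 0.27 for primed and early lineage genes (percentile 98.7), with Gata6 at 1.07 and Eomes at -1.09. Among contractile genes the matrix gene Tgfbi was the exception beyond 2-fold (1.97), and the Hox median was 0.00, or -0.39 with the floor at the 75th percentile. X-linked genes had a median of 0.01 (percentile 99.7), where the central 95% of random lists ran only from 0 to 0.000368. Of the genes compared in this pair, 20.6% had a difference of exactly 0, which holds random medians near 0. Extreme percentiles of small shifts therefore carry little weight here. Xist had 1310 intensity units on the 2n array and 2461 on the control array.

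The genes that differed between 4n 2i MEFs and control MEFs included imprinted genes, part of them shared with the 2n array, and macrophage genes. On the 4n array 542 of 10304 genes were at least 2-fold higher and 354 lower. Of these 896 genes, 11 were in the imprinted lists and 10 in the blood and macrophage list, so most belonged to neither. Grb10 (Entrez Gene 14783) was 36.8-fold lower (162.5 against 6018 intensity units), Igf2r 24.0-fold lower (126.3 against 3048) and Igf2, at 360.5 against 6870, had a log2 difference of -4.25. Mest was 9.96-fold higher (5875 against 588.8). The complement gene C1qb (Entrez Gene 12260), made by macrophages, was 22.2-fold higher (3820 against 170.9).

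Of 13 paternally expressed genes with maternal germline methylation, 6 were at least 2-fold higher on the 4n array and none was 2-fold lower. These were Mest (log2 3.32), Plagl1 (2.48), Nnat (2.00), Airn (1.53), the zinc finger gene Peg3 (1.49) and Sgce (1.04), and the median was 0.54 (percentile 99.98). By any amount 9 were higher, 3 were lower (among them Nap1l5 at -0.72) and 1 was identical, and Peg10 (0.54) lay within 2-fold here. Of 8 maternally expressed genes with maternal germline methylation, 3 were at least 2-fold lower, Grb10 (-5.20), Igf2r (-4.58) and the signal peptide peptidase gene H13 (-1.02), and none was 2-fold higher, with a median of -0.42 (percentile 1.79). Among genes with paternal germline methylation Igf2 was lower and Meg3 higher (1.20), while Rian (0.80) and Dlk1 (0.60) lay within 2-fold.

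All 10 blood and macrophage markers that passed the floor were at least 2-fold higher, with a median of 3.17 above all random lists (2.15 over all 18 markers with no floor). Of the 18, 10 reached the floor on the 4n array and 2 on the control array, so the floor favours this count and the median of 3.17. None of the 4 red cell markers was 2-fold higher. The 10 higher markers included C1qb, C1qc (4.19), the immune receptor adaptors Fcer1g (4.17) and Tyrobp (3.87), the lysosomal Cd68 (3.24) and lysozyme Lyz2 (3.10). Of 9 neural and glial genes 4 were higher and 1 lower, with a median of 0.98 (percentile 99.98). The higher ones included the glial genes Fabp7 (2.30), Erbb3 (1.96) and Sox10 (1.83). Of 10 neural and glial genes measured, 8 reached the floor on the 4n array and 6 on the control array, so the floor favours their count and median too. Fibroblast markers had a median of 0.28 (above all random lists), and 18 of 22 lay within 2-fold, with Fap (3.42) and the proteoglycan gene Lum (2.92) higher and S100a4 (-2.48) lower. Of 11 contractile genes 9 lay within 2-fold. Hox genes had a median of 0.15 (percentile 99.3), which turned to -0.67 with the floor at the 75th percentile.

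ERK pathway response genes were lower on the 4n array, 8 of 19 by at least 2-fold and none higher, with a median of -0.75 below all random lists. They included the transcription factor gene Fosl1 (-2.75), Dusp4 (-2.52), Spry4 (-1.52) and the cyclin gene Ccnd1 (-1.47). The p53 response list had a median of -0.50 (percentile 0.26), with the p53 ligase gene Mdm2 at -1.69. Cholesterol synthesis genes were all 10 lower by less than 2-fold (median -0.36, percentile 1.93). Primed and early lineage genes had a median of 0.68 (percentile 99.7), with Gata6 at 1.89 and Dnmt3a at 1.38, and the DNA methylation machinery 0.40 (percentile 99.6). Glycolysis and hypoxia genes had a median of -0.32 (percentile 1.39), with Pkm at -0.81 against Bnip3 at 1.85, and immediate early and heat shock genes -0.34 (percentile 1.73), with Fosb at -0.92. Both medians had been above 0 on the 2n array. The median of cell cycle genes was -0.23, within the central 95% of random lists, and that of X-linked genes was -0.01.

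Further genes with the largest excess on the 4n array were the calcification inhibitor Mgp (34.3-fold), the chemokine Ccl3 (21.4), Islr (20.8), the Wnt antagonist Sfrp2 (20.4), the macrophage-expressed Wfdc17 (18.3) and Ms4a6d (16.5), Capn6 (17.4), Il1rn (16.4) and Cbr2 (16.1). Further deficits were in Prl3a1 (25.7-fold), Lce1h (16.8), S100a7a (16.3), Gpr149 (16.3), Cck, the EGF receptor ligand Ereg (10.9), Cyp4a12b (10.7), Prrg4 (9.69) and the hyaluronan synthase Has2 (9.15).

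Set directly against the 2n array, the 4n 2i MEFs had more macrophage transcripts and less Igf2, Grb10 and Igf2r. Of 10280 genes 343 were at least 2-fold higher and 243 lower on the 4n array. C1qb was 33.6-fold higher (3820 against 112.7 intensity units), and all 10 blood and macrophage markers past the floor were at least 2-fold higher with a median of 3.69 (2.18 with no floor). Only 2 of the 18 markers reached the floor on the 2n array, so the floor favours this count too. Other genes high on the 4n array were Ms4a6d (23.5-fold), Fcer1g (22.7), Ccl3 (20.9), Wfdc17 (20.8), C1qc (20.4), Tyrobp (19.3), Lyz2 (13.8), the macrophage pore protein Mpeg1 (13.3), Ms4a6c (12.7) and Cd68 (12.1), together with the elastin gene Eln (15.9).

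Igf2 was 15.8-fold lower on the 4n than on the 2n array (360.5 against 5700), Grb10 14.2-fold and Igf2r 8.25-fold. Further low genes were Has2 (9.75-fold), the prostaglandin synthase Ptgs2 (8.83), the platelet chemokine Ppbp (8.65), Ereg (6.41), Lce1h (6.02), the collagen-processing Pcolce2 (5.85), Fosl1 (5.67), Prrg4 (5.62) and Uprt (5.35). All 17 cell cycle genes were lower, 1 of them by at least 2-fold (Mki67 at -1.07), with a median of -0.66 below all random lists. ERK pathway response genes had a median of -0.75, below all random lists, and the p53 list -0.67 (percentile 0.02). The medians of glycolysis (-0.41, percentile 0.24), immediate early (-0.46, percentile 0.34) and cholesterol synthesis genes (-0.37, percentile 1.32) were lower too, and those of fibroblast markers (0.14, percentile 99.9) and primed genes (0.49, percentile 99.8) higher. Paternally expressed imprinted genes with maternal germline methylation had a median of 0.06 (percentile 95.2). Of these 13 genes 7 were higher and 6 lower by any amount, and 3 were higher and 1 lower by at least 2-fold. Maternally expressed imprinted genes with maternal germline methylation had a median of -0.44 (percentile 2.30), and Hox genes 0.13 (percentile 99.7), which turned to -0.28 with the floor at the 75th percentile. Meg3 was higher by a log2 difference of 2.24 and Xist by 1.62 (4018 against 1310 intensity units). The neural and glial median was 0.64 (above all random lists), which turned to -0.32 with the floor at the 75th percentile.

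Genes that differed from control MEFs in the same direction on both 2i MEF arrays numbered 118 higher and 33 lower, of 10384 genes. Beyond the imprinted genes Mest, Igf2r and Grb10, those with the largest smaller difference were Il1rn, Des, Upk3b, Bmp4, Lrrn4, Cbr2, Rtl3, Smoc1, the collagen-associated Cthrc1 (log2 2.34 on the 2n and 3.43 on the 4n array), Capn6 and the proteoglycan gene Ogn (2.28 and 3.22) among the higher. Among the lower they were Prl3a1, S100a7a, Gpr149, Cck, Cyp4a12b, Slc13a5, Lce1h, Syt13 (-1.37 and -3.13), the growth factor gene Fgf10 (-1.35 and -2.69) and the complement regulator Cd55 (-1.33 and -1.46). Of these 151 genes, 125 differed more on the 4n array, and the median size was 1.34 on the 2n and 2.07 on the 4n array. Over all genes past the floor the 4n array also stood farther from the control, with an SD of 0.65 against 0.31 for the 2n array.

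Both differences share the control array, which could not be split. Independent lists of these sizes would share 8.24 higher and 1.51 lower genes. Unchanged arrays simulated against a shared control, with noise drawn from the 4n minus 2n differences, gave medians of 116 higher (96 to 140) and 114 lower (85 to 144) in 100 simulations. With noise drawn from the 2n minus control differences, a setting chosen after the data were seen, both medians were 32 (18 to 45 higher and 21 to 50 lower). The count of higher genes thus lay within the first simulated range and above the second, and the count of lower genes below the first and within the second. The 4n minus 2n differences had an SD of 0.54, against 0.31 for the 2n minus control differences, and hold any real difference between those arrays. The first noise is thus too large for an unchanged 2n array, and lying within its range decides nothing. The second noise in turn holds any real difference of the 2n array from the control. The correlation of the differences across genes was 0.565 against a simulated 0.50 (0.466 to 0.523, or 0.463 to 0.543 with the second noise). It lay above both ranges, which rest on equal noise in every array. The covariance was 0.115 against 0.148, or 0.0494 with the second noise. Genes are not independent replicates.

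**Figure D3:**
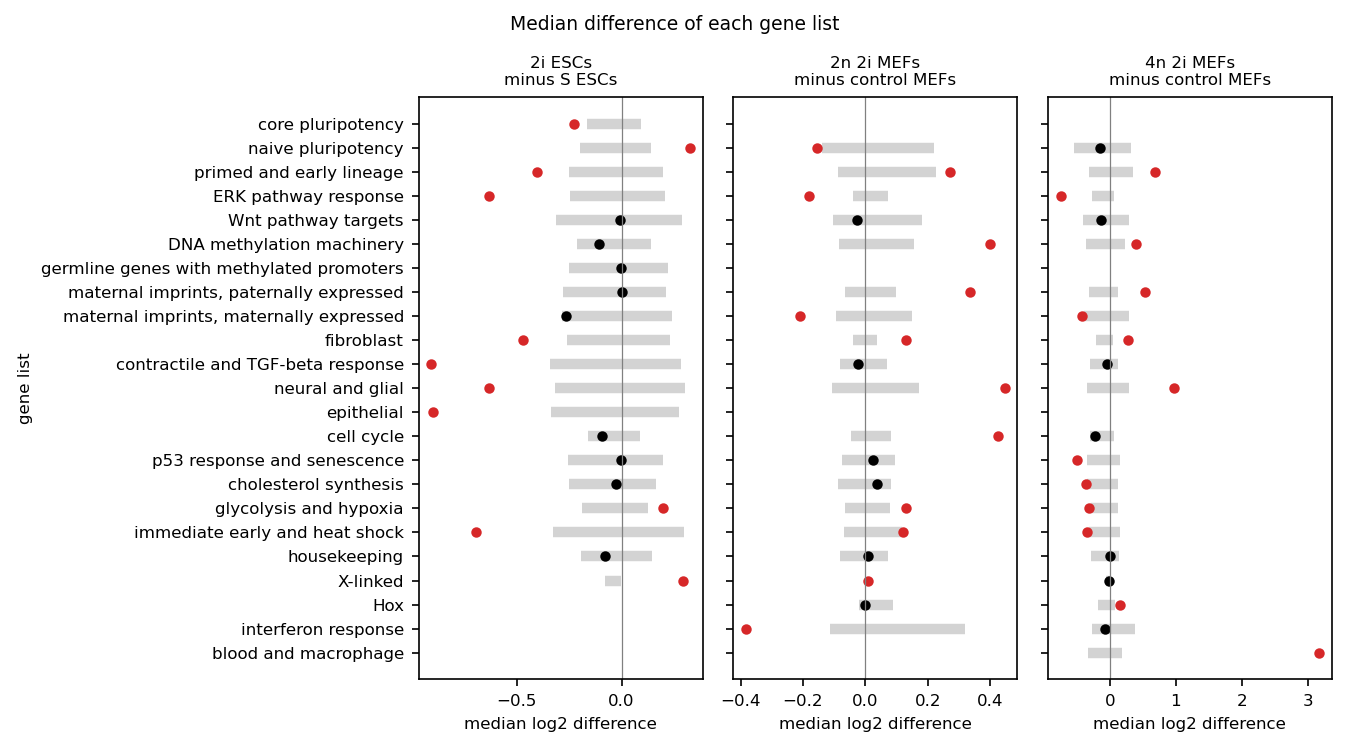
Median log2 difference of each gene list with at least 5 genes past the floor, for 3 pairs of arrays with separate axes. Grey bars span the central 95% of random lists of matched brightness, red points lie outside them and black points inside, and the blood and macrophage list lies at 3.17 in the comparison of 4n 2i and control MEFs.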

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

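Of genes past the floor and at least 2-fold different from control MEFs on both 2i MEF arrays, only Meg3 went in opposite directions. Its log2 difference was -1.04 on the 2n array and 1.20 on the 4n array, and this difference between the arrays was not tested. Probe sets outside the gene table also differed from control MEFs. At least 2-fold higher on both 2i MEF arrays were 2 of 790 probe sets of several genes past the floor, and 59 of 1444 probe sets with no gene in the platform table. Lower on both were 0 and 6. Named genes gave 118 higher and 33 lower of 10384, and all these counts share the control array.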

How the results depend on the processing

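The floor, threshold, scaling and probe set alternatives were chosen before the data were examined. Leaving out tied MEF values was chosen after the data were seen. No paired analysis was possible because each group has 1 array. With the floor at the 75th percentile, fewer genes entered and counts fell in every comparison: to 113 higher and 82 lower for 2i against S ESCs, 51 and 28 for 2n 2i against control MEFs, 267 and 222 for 4n 2i against control MEFs, 173 and 125 for 4n against 2n 2i MEFs, 69 higher on both 2i MEF arrays, and 1094 higher in ESCs than in MEFs. With a threshold of 3-fold the counts were, by construction, smaller, in the same order 95 and 87, 45 and 8, 273 and 106, 153 and 51, and 36 and 6 on both 2i MEF arrays. Without genes of identical MEF values, 1031 genes were higher in ESCs, of fewer tested. Leaving out each array gave 1632 to 1873 genes higher and 1396 to 2027 lower in ESCs, where an arm with 1 array is assumed to vary like the other. Each count and similarity stayed within 1.5 times under no floor, quantile normalization, the mean of probe sets and a pseudocount of 16. Single values that moved were Iqca (1.04) with the mean of probe sets, Aspa (2.47), Xlr (2.55) and Ms4a6c (3.18) with the pseudocount, the macrophage medians with no floor (2.15 and 2.18 on the 4n against the control and 2n arrays) and the cell cycle median of 2i against S ESCs with quantile normalization (-0.06). Under the 75th percentile floor, 3 list medians outside the central 95% changed sign: Hox genes on the 4n array against control MEFs (-0.67) and against the 2n array (-0.28), and neural and glial genes on the 4n against the 2n array (-0.32). Dimmer members left the lists there, and whether this alone was the cause was not tested.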

Other observations

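All tests in this part were chosen after the results were seen, except that the gene lists were fixed before. The macrophage and lymphocyte genes outside those lists were also chosen after.

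Differences between the ESC arrays and between the MEF arrays share no array, and some genes appeared in both. Of 11827 genes, 36 were at least 2-fold higher both in 2i than S ESCs and on the 4n than the control MEF array, where independent lists would share 14.1. The 36 include the imprinted genes Plagl1 and Meg3. Another 25 were lower in both, against 8.62 for independent lists, among them Igf2, Grb10, Dusp6, Etv4, Spry4 and Myc. These members were picked from that overlap after it was seen. Opposite directions were also more frequent than in independent lists, at 26 against 13.2 (lower in 2i ESCs and higher on the 4n array, among them Nnat and Dnmt3a) and 13 against 9.20. With the 2n in place of the 4n array the counts were 10 higher in both (4.02 in independent lists), 2 lower in both (1.06), 8 lower in 2i ESCs and higher on the 2n array (3.77) and 4 the other way (1.13). Across genes the differences had a correlation of 0.0782 with the 4n and -0.0494 with the 2n array.

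The X-linked median on the 2i ESC array lay above all 10000 random lists of matched brightness (percentile 100), so brightness does not account for it. Nor do a few strongly different genes, since 77.7% of X-linked genes lay above the median of all genes, against 43.5% to 59.1% on the autosomes. A difference in X chromosome dose between the ESC samples stays open. The median of 0.29 lay above every autosome's and under 1, the log2 difference of a doubled dose, but it is the shift itself and dose was not measured apart from it. Culture condition and cell line cannot be told apart with 1 array per condition, and allele or karyotype differences were not tested.

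With no floor, all 18 blood and macrophage genes had a median of 2.15 on the 4n 2i MEF against the control array. This lay above all 10000 random lists matched on brightness on the 2n array (percentile 100, highest random median 0.12), which argues against brightness as the cause. Of 19 macrophage genes outside the list, 11 (57.9%) passed the floor and were at least 2-fold higher than on the control array, among them Lcp1 (3.19), Pld4 (3.10) and Spi1 (3.09), and 8 such as Aif1 and Itgam did not pass it, nor did any of 9 lymphocyte genes. Macrophages among the cells of the 4n 2i MEF sample may be the source. The median past the floor was 3.16 under quantile normalization, and macrophage genes turned on in fibroblasts stay open, since no sorted cells were measured.

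On the 4n array, imprinted genes with maternal methylation beyond 2-fold went the way that loss of methylation set in the oocyte would give. Only the direction was weighed and not the size. Of the 6 paternally expressed ones, Sgce differed least (3691 against 1793 intensity units on the control array) and Mest most (5875 against 588.8). A doubled dose alone would give a size near that of Sgce and not that of Mest, so other causes stay open. Igf2 (-4.25) and Meg3 (1.20), whose germline methylation is paternal, also differed beyond 2-fold from control MEFs on that array. All 9 members of the maternal methylation lists beyond 2-fold (100%) were higher if paternally expressed and lower if maternally expressed. By any amount, 9 of 13 paternally expressed genes were higher, 3 lower and 1 identical, and 7 of 8 maternally expressed genes were lower and 1 higher. Brightness does not account for the median of the paternally expressed list, at percentile 99.98. The 11 imprinted genes beyond 2-fold on the 4n array differed less from the control on the 2n array, while Peg10 differed more there. Control-like cells mixed with 4n-like cells could give such smaller differences. The weight of the 4n array needed for the 2n value had a range of 1.08 over the 11 genes. It ran from -0.40 (Meg3) through 0.18 (Igf2) to 0.63 (Grb10) and 0.68 (Igf2r), which argues against a mix of these profiles as the whole cause. Of 232 genes at least 4-fold different between the 4n and control arrays, imprinted ones included, the 2n value lay between in 187 (80.6%). Their median weight was 0.19. An unchanged 2n array simulated against the shared control, with noise from the 2n minus control differences, gave 49.1% between (40.7% to 56.6%). Its median weight was 0 (at most 0.00503). An unchanged 2n array with noise can thus produce part of the share but not the median weight, which leaves a mix in part open. With 2 SD of noise the weight of Igf2 reached at most 0.39 and that of Igf2r fell no lower than 0.53, and a mix with 2i-derived cells unlike the 4n sample, or a difference between lines, stays open, as does methylation itself, which was not analysed here.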
